A study of Mus musculus with 11 samples.

How the data were processed

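RNA from MC38 mouse tumours and from T cells sorted out of such tumours was measured by bulk RNA sequencing in 11 libraries. The tumour cells carried a control short hairpin RNA (shNC) or one against Fgf21 (shFgf21). Sorted T cells gave 3 shNC and 2 shFgf21 libraries, and tumours gave 3 libraries of each kind. Groups were taken from the sample titles. One shFgf21 sorted library, replicate 2, has a genotype label that names FGF22 where the title matches its partner, and it was kept in the shFgf21 group. The titles of the sorted libraries join several animal-like numbers, and nothing in the labels says how they were pooled. The tumour libraries are labelled both as tumour tissue and as the MC38 line. Their leukocyte gene levels, given below, argue against whole tumour tissue. Whether the cells came from grown tumours or from culture is open. The labels do not say that replicates came from separate animals, so p-values measure the spread between these libraries, which may be partly technical.

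The authors deposited whole-number counts per gene for 55487 genes, beside FPKM values of the same libraries. The genome build was mm10, per the submitters' processing notes. The kit's strandedness, the aligner, the counting program and the annotation release are not given in the sources used here. Coordinates are those the deposited table lists. Of the listed gene identifiers, 99.4% were found in a GENCODE M21 annotation of the same build. The deposited FPKM values equal the count divided by a fixed gene length and by the library's total over listed genes. Over 9655 genes with more than 100 counts in every library, the length this implies differed between libraries by at most 8.4e-04%. The FPKM values hold no information beyond the counts and were not tested. The table gives no gene lengths and no strand of the reads, so overlapping and antisense genes cannot be separated. In 120 cases a gene name was listed again under another identifier, and the identifier with the most counts was used for the gene lists.

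Counts were analysed as deposited in R 4.3.3 with edgeR 4.0.16. Within each kind of sample, genes were kept by filterByExpr, libraries were scaled by TMM, and shFgf21 was compared with shNC by the quasi-likelihood F-test. P-values were adjusted by the Benjamini-Hochberg method and the threshold was an adjusted p of 0.05. Standard errors of log2 fold changes were the fold change divided by the square root of F. CPM values beside a fold change use the TMM factors of that kind of sample, and levels compared across all libraries use TMM factors over the 11 libraries. The difference of the knockdown effect between sorted T cells and tumours was tested as an interaction in a fit of all 4 groups.

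Gene lists, 32 in all with 382 entries, were fixed before the data were examined, together with the groups, the tests, the rule for named genes and all alternatives not said to be added later. Lists with at least 3 tested genes were tested by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided. Camera with an estimated correlation and fry were run beside it. The text names Fgf21, up to 10 genes per direction with the largest fold change among those past the threshold, without overlap between groups and at a mean of at least 10 CPM. Where fewer than 5 passed in a direction, those with the smallest p-values fill up to 5 and are said not to pass. It further names up to 4 members per reported list and a fixed set of T cell, cholesterol and FGF receptor genes, some of which are not reported here. Predicted genes and antigen receptor segments were left out of the ranked part. Other genes named are said to have been chosen after their values were seen.

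Alternatives were the median-ratio size factors, no filter on low counts, a filter at a mean of 5 CPM, the DESeq2 1.42.0 Wald test, limma voom with sample quality weights, all 4 groups in one fit, leaving out each library in turn and, in tumours, the number in the title as a block. Alternatives planned for normalized values did not apply, since counts were deposited. Robust moderation and a fit with the T cell identity level as a covariate were added after seeing the data.

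Library totals ran from 14944013 to 19099350 counts. A count of 0 allows a level of up to 3 counts, which is 0.157 to 0.201 CPM across the libraries, and this limit covers counting error only. The tests were run first on simulated counts with the means, library sizes and dispersions of the real data and 200 changed genes. The changed genes were drawn from those with a mean of at least 10 CPM, so the shares recovered do not cover genes below that level. For sorted T cells, on 16131 genes, 20.9% of genes changed 1.5-fold, 91.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, and 13.0% of the calls were false. For tumours, on 14710 genes, these shares were 4.48%, 64.2% and 100%, with 9.68% false calls. For the interaction, on 14511 genes, 0% of 1.5-fold, 22.2% of 2-fold and 98.4% of 4-fold changes were recovered, with 7.41% false calls. A share of false calls above the nominal 5% is thus a limit of these tests at this size. Lists were simulated too, with genes drawn independently. With 18 cytotoxic members raised 2-fold in sorted cells, camera gave adjusted p = 1.8e-20 with the preset correlation and 0.0558 with an estimated one. With 19 cholesterol biosynthesis members raised 2-fold in tumours, camera gave adjusted p = 3.9e-24 and 0.0134.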

Results

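The series asked how FGF21 made by tumour cells affects tumour-infiltrating CD8+ T cells, with cholesterol metabolism named in its title. MC38, a mouse colon carcinoma line, carried a control hairpin (shNC) or a hairpin against Fgf21 (shFgf21). Gene counts were deposited for T cells sorted from such tumours (3 shNC and 2 shFgf21 libraries) and for libraries labelled as tumours (3 and 3). Total counts per library were 14944013 to 16654736 in shNC sorted cells, 15257217 to 16184050 in shFgf21 sorted cells, 14968855 to 19099350 in shNC tumours and 15451669 to 16972761 in shFgf21 tumours. Log2 CPM correlated at 0.967 to 0.987 between libraries of 1 group, at 0.972 to 0.987 between shNC and shFgf21 libraries of 1 kind of sample and at 0.781 to 0.825 between sorted cells and tumours, across 14767 genes, which are not independent replicates. The first principal component held 85.3% of the variance and separated the 2 kinds of sample. No pair of libraries agreed within sampling noise (a chi-square of at least 13.4 per gene).

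Fgf21 itself (chromosome 7, 45613886 to 45615490, mm10) was at the detection limit in every library. The shNC tumours held 0, 2 and 1 counts of it, and all shFgf21 tumours and all sorted libraries held 0. A count of 0 allows at most 0.177 to 0.201 CPM in these libraries. The knockdown could therefore not be checked at this depth, and the group labels rest on the titles. Klb, the co-receptor that FGF21 needs, had 0 to 4 counts per library. Fgfr1, an FGF receptor, was expressed in tumours at 371 ± 55.8 CPM in shNC and 340 ± 17.7 CPM in shFgf21 (SD, n = 3 each), a log2 difference of -0.13 ± 0.15 (SE; edgeR quasi-likelihood, adjusted p = 0.937).

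The libraries labelled as sorted T cells held T cell transcripts at low levels beside abundant macrophage and tumour-type transcripts. Cd3e, a chain of the T cell receptor complex, was at 52.9 ± 17.9 CPM in shNC and 35.4 ± 0.932 CPM in shFgf21 sorted libraries (SD, n = 3 and n = 2), and Cd8a was at 73.4 ± 32.6 and 46.3 ± 15.4 CPM. Lyz2, the macrophage lysozyme, was at 6557 ± 756 and 9339 ± 211 CPM. The 12 macrophage and monocyte markers took 1.25% ± 0.117 and 1.70% ± 0.0639 of all counts, and the 18 T cell identity markers took 0.0706% ± 0.0233 and 0.0545% ± 0.00677. Per library, the count ratio of the first list to the second was 12.6, 16.3 and 30.4 in shNC replicates 1 to 3 and 33.3 and 29.4 in shFgf21 replicates 1 and 2. Transcripts abundant in the tumour libraries were also present, with Fn1 (fibronectin) at 5155 ± 279 and 5773 ± 1144 CPM and Vim (vimentin) at 3607 ± 243 and 3404 ± 144 CPM.

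The libraries labelled as tumours held leukocyte and T cell markers at or near the detection limit, and the median macrophage marker was at 0.597 CPM. Ptprc, the leukocyte antigen CD45, was at 0.490 ± 0.420 CPM in shNC and 0.215 ± 0.202 CPM in shFgf21 tumours (SD, n = 3 each), against 279 ± 19.3 and 281 ± 14.2 CPM in the sorted libraries. Cd3e had no counts in any tumour library. Over the tumour libraries Ptprc was at 0 to 0.975 CPM and Csf1r, a macrophage marker, at 0.115 to 0.676 CPM. These levels argue against whole tumour tissue with its leukocytes in the libraries labelled as tumours. Whether the cells were cultured or taken from grown tumours without leukocytes stays open. Lyz2 was at 6.22 ± 3.93 and 3.89 ± 1.37 CPM, and Cd14, also of the macrophage list, was at 26.2 ± 1.14 and 28.2 ± 2.32 CPM (scaled over tumours). Other genes known from immune cells were present, with Cd74 at 40.1 to 378 CPM and Cxcl9 at 52.1 to 190 CPM over the tumour libraries. The NK cell list took 0.00476% and 0.00541% of counts in shNC and shFgf21 tumours, against 0.00411% and 0.00297% in sorted libraries. Its member Ncr1 had no counts in tumours, and fewer than 3 members passed the filter there, so few genes carried this share. The dendritic cell list took 0.0297% and 0.0270% in tumours against 0.0243% and 0.0173% in sorted libraries, and its member Fscn1, an actin-bundling gene, was at 282 ± 48.8 and 259 ± 97.9 CPM in tumours (scaled over tumours). Col3a1, a fibrillar collagen, was at 3540 ± 155 and 3273 ± 665 CPM, while the epithelial genes Epcam and Krt8 stayed at or below 1.04 CPM. No test was run on these levels across kinds of sample.

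**Figure D1:**
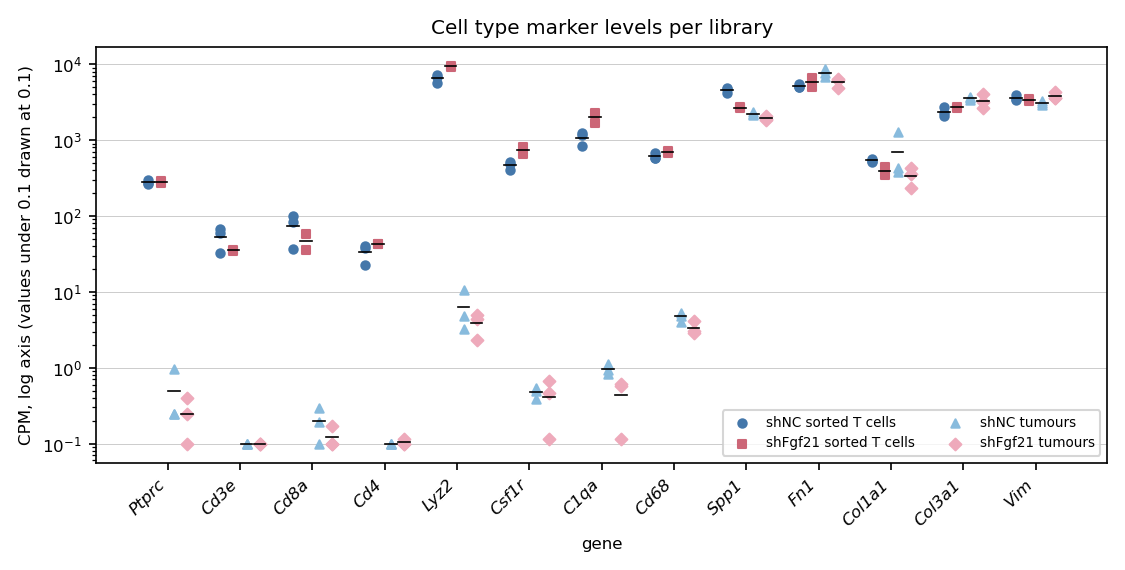
Levels of 13 marker genes (x axis) in CPM scaled over all 11 libraries (y axis, log scale, values under 0.1 drawn at 0.1). Each point is a library, coloured by group, and each bar the mean of a group's drawn values. Ptprc, T cell and macrophage genes are higher in the sorted libraries than in tumours. Among them Cd3e, Cd8a and Cd4 are at 22.8 to 99.9 CPM in sorted libraries, against at least 5718 CPM for Lyz2. Fn1, Col3a1 and Vim are high in both.

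The first comparison asked which genes differ between T cells sorted from shFgf21 and from shNC tumours. Of 16454 genes tested, 13 passed the threshold, 3 higher and 10 lower in shFgf21 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 1842 had an unadjusted p under 0.05. The higher genes were Cfb, complement factor B, Cxcl9, an interferon-induced chemokine that attracts T cells, and Aoah, a lipopolysaccharide-inactivating enzyme. Cxcl9 (chromosome 5, 92321347 to 92328079) rose from 285 ± 32.0 to 615 ± 8.64 CPM, a log2 fold change of 1.11 ± 0.11 (SE, adjusted p = 0.0296). Cfb (chromosome 17, 34856374 to 34862518) rose from 73.1 ± 10.9 to 190 ± 7.99 CPM (1.38 ± 0.13, adjusted p = 0.0296). Aoah (chromosome 13, 20794113 to 21036617) rose from 64.8 ± 3.02 to 123 ± 2.69 CPM (0.92 ± 0.09, adjusted p = 0.0296).

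Prf1, the pore-forming protein of cytotoxic lymphocytes (chromosome 10, 61297833 to 61304680), fell from 65.1 ± 3.21 to 28.1 ± 4.11 CPM, a log2 fold change of -1.21 ± 0.13 (SE, edgeR adjusted p = 0.0296). Mmp12, the macrophage elastase (chromosome 9, 7344381 to 7369499), fell from 1826 ± 258 to 807 ± 33.9 CPM (-1.18 ± 0.14, adjusted p = 0.0479). Col12a1, a collagen, fell from 59.4 ± 3.68 to 28.3 ± 3.72 CPM (-1.07 ± 0.13, adjusted p = 0.0489). Snrk, Tmem70, Fam107b, Pcyt1a and Tnpo1 also fell, with log2 fold changes of -1.71, -1.35, -1.29, -1.26 and -1.20. The remaining lower genes were the small RNA genes Mir8114 and Snord16a, named after their values were seen, with 222 and 153 counts over the shNC libraries and 2 each over the shFgf21 libraries. Each overlaps a listed gene that moved the other way, by 8.51 and 6.67 times the change in CPM of Mir8114 and Snord16a. C3 (0.85 ± 0.11) and Gbp2 (0.71 ± 0.09) were the next higher genes and did not pass (both adjusted p = 0.0562). All 13 genes had no overlap between groups, which was so for 29.4% of the genes tested against 20% by chance.

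**Figure D2:**
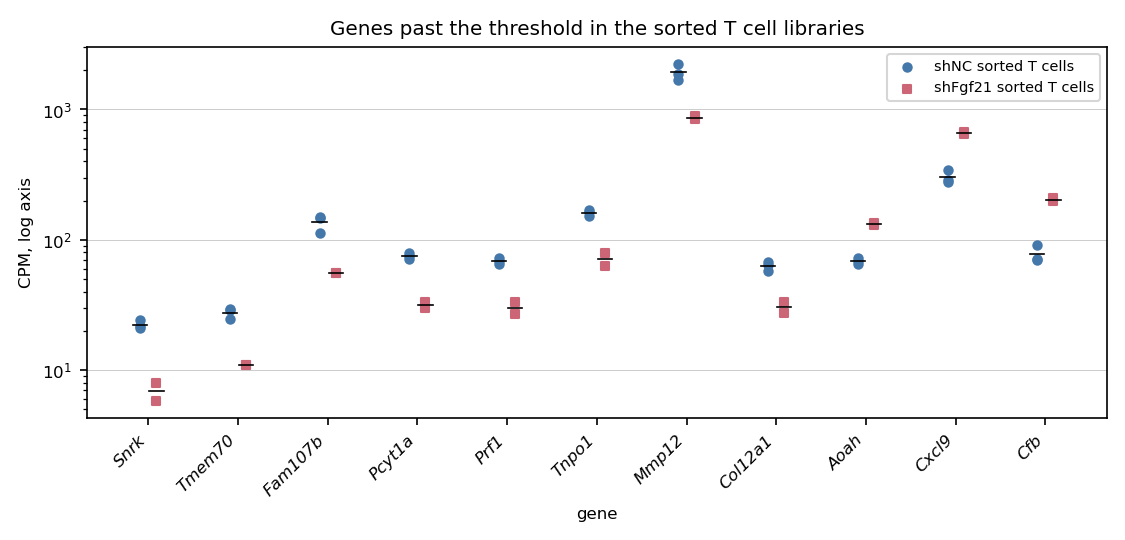
CPM scaled over all 11 libraries (y axis, log scale) of the 11 longer genes past the threshold in sorted T cell libraries (x axis). Points are libraries and bars are group means. In each gene the 3 shNC and the 2 shFgf21 libraries do not overlap, with Aoah, Cxcl9 and Cfb higher and the others lower in shFgf21.

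These calls were lost without either shFgf21 sorted library. Without replicate 2, the library whose genotype label names FGF22, 0 genes passed, with 1060 at an unadjusted p under 0.05, and without replicate 1 a single gene passed that was not among the 13. Whichever of the 5 libraries was left out, the log2 fold change was 1.31 to 1.51 for Cfb, 1.06 to 1.20 for Cxcl9, -1.37 to -1.07 for Prf1 and -1.33 to -1.19 for Pcyt1a. Without shNC replicate 1 or replicate 3, 28 and 34 genes passed. DESeq2 called 246 genes, 153 higher and 93 lower, and a fit of all 4 groups called 1.

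Genes of cytotoxic lymphocytes were lower as a list in the shFgf21 sorted libraries. Of 19 members, 17 were lower, 1 passed over all genes, and 10 lower and 2 higher members passed adjusted over the list alone (median log2 fold change -0.86, camera adjusted p = 9.5e-05). Its adjusted p = 0.603 with an estimated correlation, so the call was lost. That test also missed a simulated 2-fold rise of this list (camera adjusted p = 0.0558), so it cannot decide for this list. Other lists were not simulated in sorted cells. Among the lists called in sorted cells, the estimated correlation ran from 0.106 for this list to 0.709 for erythroid cells. Each was above the preset 0.01, so the p-values with the preset may be too small. With the T cell identity level as a covariate, chosen after seeing the data, the median was -0.48 (camera adjusted p = 6.0e-05). Beside Prf1, the granzymes Gzmb (-0.77 ± 0.16) and Gzma (-1.22 ± 0.29) and the cytokine Ifng (-1.36 ± 0.41) did not pass over all genes (edgeR adjusted p = 0.192, 0.236 and 0.313), and the chemokine Ccl5 was at 0.83 ± 0.14 in the other direction (adjusted p = 0.130). Without shNC replicate 3 Gzmb and Ifng passed (adjusted p = 0.0437 and 0.0188), and Gzma was at -1.82 to -0.79 without 1 library. The T cell identity list was not called, with 14 of 18 members lower (median -0.32, adjusted p = 0.166), nor were NK cells, with 5 of 6 lower (median -0.84, adjusted p = 0.0624). Without shNC replicate 3, both were called (adjusted p = 8.8e-08 and 0.00232), and NK cells also without shFgf21 replicate 1 (adjusted p = 0.0119).

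Macrophage and antigen presentation genes were higher as lists. Of 12 macrophage and monocyte markers, 11 were higher and 7 passed adjusted over the list alone (median 0.54, camera adjusted p = 1.2e-05, adjusted p = 0.603 with an estimated correlation), with Ms4a7 at 0.77 ± 0.11, the F4/80 gene Adgre1 at 0.79 ± 0.12 and the complement gene C1qa at 0.88 ± 0.19. Of 8 MHC class II genes, 7 were higher and 7 passed adjusted over the list alone (median 0.79, adjusted p = 1.2e-05, adjusted p = 0.603 with an estimated correlation), with H2-Eb1 at 1.08 ± 0.17 and Cd74 at 0.69 ± 0.12. Of 13 MHC class I genes, 12 were higher and 4 passed adjusted over the list alone (median 0.30, adjusted p = 1.97e-04, adjusted p = 0.603 with an estimated correlation). No single member of these lists passed over all genes, but H2-Eb1 did without shNC replicate 1 (edgeR adjusted p = 0.0481). Without shFgf21 replicate 2 the class I median was 0.17 and its call was lost (adjusted p = 0.0559).

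Neutrophil genes were lower, with 5 of 6 members lower and 5 passing adjusted over the list alone (median -1.98, camera adjusted p = 1.9e-04, adjusted p = 0.603 with an estimated correlation). S100a9 was at 33.9 ± 17.2 CPM in shNC and 6.04 ± 0.880 CPM in shFgf21, and S100a8 at 21.3 ± 8.73 and 6.69 ± 0.901 CPM. S100a9 passed over all genes without shNC replicate 2 (edgeR adjusted p = 0.0476). Hypoxia genes were lower in 9 of 10 members, 2 of them adjusted over the list alone (median -0.33, adjusted p = 0.0108, adjusted p = 0.656 with an estimated correlation), led by the vasodilator peptide gene Adm at -1.46 ± 0.25. The hypoxia call was lost without shNC replicate 3 (adjusted p = 0.224) or shFgf21 replicate 2 (median -0.15, adjusted p = 0.236), and the median was -0.63 without shFgf21 replicate 1 (adjusted p = 0.00184). Of 11 listed epithelial genes, 3 were tested and all were lower (median -1.05, camera adjusted p = 0.0179). Among these Epcam had means of 1.40 and 0.585 CPM in shNC and shFgf21, and Lgals4 was at -0.10 ± 0.26. Of 5 listed erythroid genes, 3 globin genes were tested and all were higher (median 1.65, camera adjusted p = 0.0108). Both lists had adjusted p = 0.603 with an estimated correlation. The 3 globin genes had means of at most 2.26 CPM. Without shFgf21 replicate 2 both calls were lost (medians -0.93 and 0.90, adjusted p = 0.140 and 0.127), and the epithelial call also without shNC replicate 2 (adjusted p = 0.0725).

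Cholesterol biosynthesis genes were not called as a list in the sorted libraries. Of 20 cholesterol biosynthesis genes, 15 were higher and none passed, over all genes or adjusted over the list alone (median 0.13, camera adjusted p = 0.0802). The list was called without shNC replicate 1 (adjusted p = 0.0330) and without shFgf21 replicate 1 (adjusted p = 0.0334). Sqle, squalene epoxidase, was at a log2 fold change of 0.19 ± 0.25 (SE, edgeR adjusted p = 0.823). The sterol regulators Srebf2 (0.39 ± 0.11) and Srebf1 (0.10 ± 0.11) did not pass (adjusted p = 0.308 and 0.758). Apoe, the macrophage and lipoprotein apolipoprotein, was at 812 ± 251 and 3133 ± 1095 CPM (1.95 ± 0.29, adjusted p = 0.0913).

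Exhaustion and T cell state genes did not pass. Of 17 exhaustion genes, 12 were higher and none passed over all genes (median 0.07, camera adjusted p = 0.610). Adjusted over the list alone, 1 passed. Of the 18 listed, 8 passed the filter in tumours, where Cd3e had no counts. Nr4a1, Nr4a2 and Havcr2 were at 436, 72.2 and 86.6 CPM in shNC sorted libraries and at 513, 48.9 and 11.7 CPM in shNC tumours. The rest of the 8 were at most 9.07 CPM in shNC tumours. RNA of this list may come from other cells, so its level may not be that of T cells alone. Pdcd1, the PD-1 gene, was at 18.4 ± 8.09 and 11.6 ± 4.84 CPM (-0.66 ± 0.40, edgeR adjusted p = 0.586). Lag3 (-0.44 ± 0.28), Havcr2 (0.13 ± 0.10), Tox (0.06 ± 0.38) and Tcf7 (0.15 ± 0.12) had adjusted p of 0.605, 0.670, 0.970 and 0.698. Cd8a was at -0.68 ± 0.40, Cd4 at 0.34 ± 0.23 and the regulatory T cell factor Foxp3 at 0.28 ± 0.13 (adjusted p = 0.572, 0.626 and 0.485). Leaving out 1 library at a time moved the log2 fold change to between -1.17 and -0.29 for Pdcd1, -0.71 and -0.23 for Lag3, 0.038 and 0.22 for Havcr2, 0.066 and 0.23 for Tcf7, -1.07 and -0.37 for Cd8a, 0.11 and 0.49 for Cd4 and 0.16 and 0.40 for Foxp3, and none of these passed. In all, 30 lists were tested in sorted cells and 8 were called, 4 in each direction, against 0 with an estimated correlation and 0 by fry.

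The second comparison asked which genes differ between shFgf21 and shNC tumours. Of 14950 genes tested, 5 passed, 4 higher and 1 lower in shFgf21 (edgeR quasi-likelihood, Benjamini-Hochberg adjusted p under 0.05), and 930 had an unadjusted p under 0.05. Abl1, a tyrosine kinase gene (chromosome 2, 31688376 to 31804227), rose from 46.7 ± 4.32 to 158 ± 16.3 CPM (SD, n = 3 each), a log2 fold change of 1.76 ± 0.14 (SE, adjusted p = 0.0123). The other 4 genes, named after their values were seen, were S100a3, a calcium-binding protein gene, at 1.19 ± 0.636 and 13.7 ± 2.59 CPM, Gm41787 and Gm20716 with 0 counts in shNC and 165 and 797 in shFgf21 tumours, and Gm45713 with 152 and 1 counts. Gm20716 overlaps a listed gene that moved the other way by 0.673 times its change in CPM. The next higher genes were Oxct1, a ketone body enzyme gene, at 1.12 ± 0.13, Lrch4 at 2.82 ± 0.35, Il2rg, a shared cytokine receptor chain, at 1.26 ± 0.18 and Amigo2 at 1.41 ± 0.21, and none passed (adjusted p = 0.0509, 0.0509, 0.113 and 0.135). The next lower genes were Slc6a9, a glycine transporter gene, at -1.10 ± 0.14 and Amd1, a polyamine synthesis gene, at -2.45 ± 0.37 (adjusted p = 0.0554 and 0.136), then Serpinf1 at -1.05 ± 0.17, Sned1 at -1.08 ± 0.18 and the cysteine synthesis gene Cth at -1.39 ± 0.23 (each adjusted p = 0.139). Without shNC tumour replicate 1, Lrch4 and Sned1 passed (adjusted p = 0.0170 and 0.0391). The immune gene Cd274, which encodes PD-L1, was at 37.0 ± 16.2 and 61.7 ± 15.7 CPM (0.74 ± 0.31, adjusted p = 0.795). Sqle was at 0.23 ± 0.27 on the log2 scale (adjusted p = 0.938).

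In the sorted libraries Abl1 was also at separate levels, at 42.4, 42.5 and 151 CPM in shNC and at 167 and 149 CPM in shFgf21 (edgeR adjusted p = 0.516). Without shNC tumour replicate 6 or shFgf21 tumour replicate 3, 0 genes passed, with 967 and 746 at an unadjusted p under 0.05, and Abl1 had adjusted p of 0.0535 and 0.106, while its log2 fold change was 1.70 to 1.84 whichever library was left out. Over all alternatives the adjusted p of Abl1 ran from 1.0e-21 to 0.158. Without shFgf21 tumour replicate 1 or replicate 2, 3 and 2 genes passed, and without shNC tumour replicate 1, 8 passed. DESeq2 called 115 genes, 42 higher and 73 lower, and limma voom called 21. All 5 genes had no overlap between groups, which was so for 11.6% of genes tested against 10% by chance.

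Proliferation, chemokine and antigen presentation genes were higher as lists in shFgf21 tumours, with no member past the threshold over all genes. Of 22 cell cycle genes, 21 were higher (median 0.31, camera adjusted p = 2.04e-06, adjusted p = 0.421 with an estimated correlation), with Birc5 at 0.55 ± 0.16 and Aurkb at 0.46 ± 0.14, and 0 passed adjusted over the list alone. Of 12 cytokine and chemokine genes, 10 were higher and 5 passed adjusted over the list alone (median 0.54, adjusted p = 3.9e-05, adjusted p = 0.421 with an estimated correlation), with the monocyte attractants Ccl2 at 1.33 ± 0.26 and Ccl7 at 1.07 ± 0.29 and the growth factor gene Csf2 at 1.06 ± 0.21. All 7 MHC class II genes (median 0.995, adjusted p = 6.7e-05) and all 13 class I genes (median 0.33, adjusted p = 3.1e-04) were higher, with H2-DMa at 0.95 ± 0.38 and Psmb8 at 0.60 ± 0.20, and none passed adjusted over the list alone. With an estimated correlation, adjusted p = 0.421 for class II and adjusted p = 0.509 for class I. In shNC replicate 2 Cd74 was at 40.1 CPM, against 189 and 263 CPM in the other shNC tumours. Without that library the medians were 0.58 for class II, 0.27 for cytokines and 0.19 for cell cycle (adjusted p = 8.1e-05, 0.00148 and 0.00153), and class I was at 0.18 with its call lost (adjusted p = 0.0753). Without shNC replicate 1 the cytokine and class I medians were 1.11 and 0.52 (adjusted p = 7.3e-09 and 1.1e-05), and without shFgf21 replicate 1 the class I median was 0.14 (adjusted p = 0.0268).

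Lipid synthesis genes were higher in tumours as lists. Of 20 cholesterol biosynthesis genes, 18 were higher (median 0.24, camera adjusted p = 0.00206), with Acat2 at 0.45 ± 0.25 and Idi1 at 0.53 ± 0.30, and of 14 fatty acid synthesis genes 11 were higher (median 0.20, adjusted p = 0.0306), with Scd2 at 0.83 ± 0.31. None passed over all genes or adjusted over the list alone, and both lists had adjusted p = 0.509 with an estimated correlation. Without shNC replicate 2 both calls were lost (medians 0.073 and 0.11, adjusted p = 0.233 and 0.489), and without shNC replicate 6 the cholesterol biosynthesis median was 0.39 (adjusted p = 2.3e-05). The fatty acid call was also lost without shFgf21 replicate 1 (adjusted p = 0.0786) or replicate 2 (median 0.084, adjusted p = 0.0762). Cholesterol efflux and storage genes were lower in 6 of 8 members, 2 adjusted over the list alone (median -0.27, adjusted p = 0.00648, adjusted p = 0.421 with an estimated correlation), with the efflux pump gene Abca1 at -1.19 ± 0.26 and Soat2 at -1.39 ± 0.37. That call was lost without shFgf21 replicate 1 (adjusted p = 0.0567).

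Hypoxia, glycolysis, fibroblast and endothelial gene lists were lower in shFgf21 tumours. The list names do not show that stroma cells were present. Col3a1 was at 2671 to 3986 CPM in the tumour libraries, where Ptprc was at 0 to 0.975 CPM. Hypoxia genes were lower in 7 of 10 members, 6 adjusted over the list alone (median -0.47, camera adjusted p = 0.00194, adjusted p = 0.421 with an estimated correlation), with Car9 at -1.19 ± 0.22 and Adm at -2.35 ± 0.49. Glycolysis genes were lower in 12 of 15, 1 adjusted over the list alone (median -0.19, adjusted p = 0.00264, adjusted p = 0.421 with an estimated correlation), with the glucose transporter gene Slc2a1 at -0.68 ± 0.15. Fibroblast genes were lower in 7 of 8, 2 adjusted over the list alone (median -0.75, adjusted p = 0.00207), and the integrated stress response in 9 of 15, 0 adjusted over the list alone (median -0.24, adjusted p = 0.0494). The last 2 lists also had adjusted p = 0.421 with an estimated correlation. Of 8 listed endothelial genes, 4 were tested and all were lower, 1 adjusted over the list alone (median -1.34, adjusted p = 0.00520, adjusted p = 0.432 with an estimated correlation). These 4 had group means of at most 6.01 CPM. Interferon-stimulated genes were lower in 14 of 18, 1 adjusted over the list alone (median -0.33, adjusted p = 0.00493, adjusted p = 0.509 with an estimated correlation).

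Library shNC tumour 1 stood apart in the fibroblast and endothelial lists. Col1a1 was at 1273 CPM there, at 380 and 426 CPM in the other shNC tumours and at 233 to 424 CPM in the shFgf21 tumours. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty summed to 4.48 CPM there, 0.489 to 1.45 CPM in the other tumours and 82.1 to 102 CPM in sorted libraries. Without it the fibroblast median was -0.39 (camera adjusted p = 0.0376), and the endothelial, interferon and stress response calls were lost (medians -0.33, -0.20 and -0.14, adjusted p = 0.175, 0.307 and 0.406). The fibroblast median was -1.27 without shNC replicate 6 and -1.23 without shFgf21 replicate 1 (adjusted p = 3.3e-04 and 0.00179). The interferon call was also lost without shFgf21 replicate 3 (median -0.058, adjusted p = 0.474), and the stress response call without any 1 of the shFgf21 replicates (adjusted p = 0.0788 to 0.138). Of 22 lists tested in tumours, 13 were called, 6 higher and 7 lower. With an estimated correlation 0 were called, and fry called 1, the cholesterol efflux and storage list (fry adjusted p = 0.00350). The estimated correlation of the called lists ran from -0.119 (cholesterol efflux and storage) to 0.941 (MHC class II), against the preset 0.01. In the tumour simulation, with independent genes, that test did find a 2-fold rise of the cholesterol biosynthesis list (camera adjusted p = 0.0134).

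**Figure D3:**
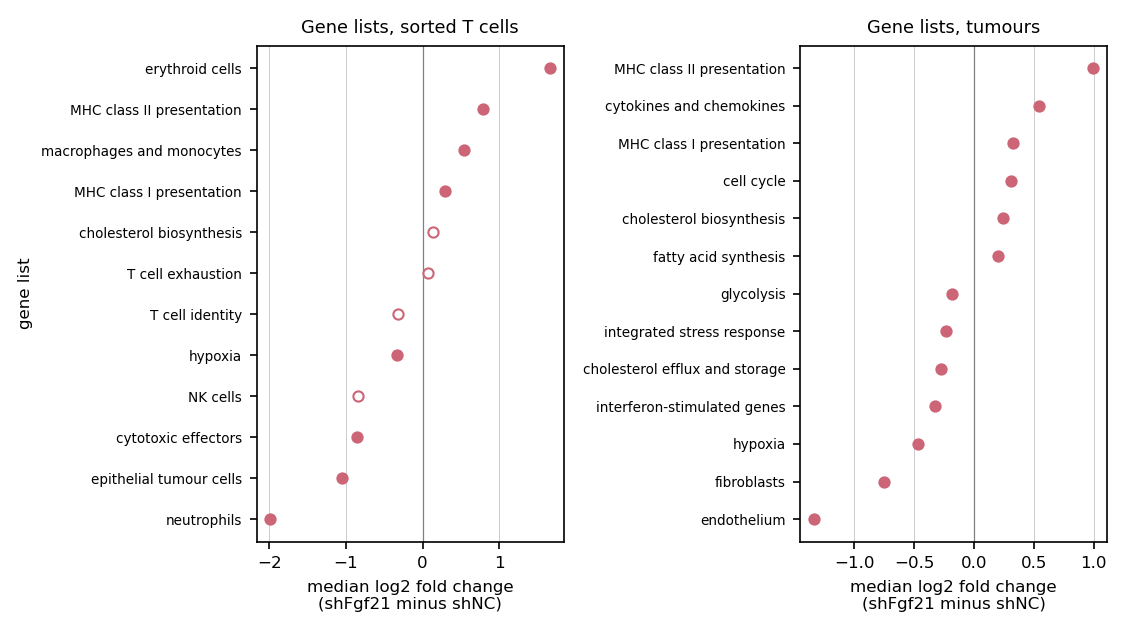
Median log2 fold change (x axis, shFgf21 minus shNC) of the members of the called gene lists (y axis) in sorted T cell libraries (left, with 4 lists that were not called) and tumours (right). Filled points passed camera with the preset correlation and open points did not. None of the filled points passed with an estimated correlation.

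The third comparison asked whether the effect of the knockdown differed between sorted cells and tumours. Of 17327 genes tested, 1 passed, Mir8114, with an effect lower in sorted cells by -5.93 on the log2 scale (edgeR interaction, adjusted p = 0.00794), and 826 had an unadjusted p under 0.05. Mir8114 lies under 10 CPM and is named because it is the only gene past the threshold. Without either shFgf21 sorted library 0 genes passed, with 717 and 591 at an unadjusted p under 0.05, and DESeq2 called 36. The effect on Cxcl9 differed by 0.42 (unadjusted p = 0.365, not past the threshold), so it was not shown to differ between the kinds of sample. Prf1 was at 0 to 0.195 CPM in tumours, so its effect there could not be compared.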

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

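All tests of this part but the interaction and the split counts of sorted-cell genes and tumour lists were chosen after the results were seen, as were the bounds of the source ratio and, after a search with another definition, that of 2 levels. The interaction test singled out Mir8114, whose effect in sorted cells minus that in tumours was -5.93 on the log2 scale. Mir8114 overlaps 2 listed genes, 1 of which moved the other way in sorted cells by 8.51 times the change in CPM of Mir8114. By camera on the interaction, 11 of 30 lists also differed, and 0 did with an estimated correlation (smallest adjusted p = 0.366). The median differences were -0.36 for cell cycle, -0.14 for neutrophils, -0.50 for NK cells and -0.38 for cytokines and chemokines. They were 0.64 for cholesterol efflux and storage, 0.85 for macrophages and monocytes, 0.45 for CD4 and regulatory T cells, 0.57 for fibroblasts, 1.08 for endothelium and 0.32 for interferon-stimulated genes. For cytotoxic effectors the test went down while the median was 0.28. In tumours neutrophil genes held 0 to 7 counts per library, CD4 and regulatory T cell genes 117 to 191 and endothelial genes 95 to 412. The median macrophage marker was at 0.597 CPM there. For these lists the tumour side lies near the detection limit. The NK cell list held 723 to 967 counts per tumour library, though its member Ncr1 had 0. Fewer than 3 of its members passed the filter in tumours, so few genes carried these counts and the list was not tested there. Its median difference thus also rests on members near the detection limit in tumours. Cell cycle, cytokine and fibroblast lists held abundant genes, with Top2a at 582, Ccl2 at 589 and Dcn at 1772 CPM in shNC tumours. Since 0 of the 11 lists were called with an estimated correlation, they were not shown to be different effects. No group held 4 or more libraries, so single libraries were not tested as outliers.

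The sorted libraries carried tumour-type and macrophage transcripts far above T cell transcripts. A swap of all sorted and tumour labels is argued against, since T cell identity counts in tumours were 0.00328 of those in sorted libraries. Among 3649 genes of at least 50 CPM in every tumour library, the 1st percentile of the sorted to tumour ratio was 0.498, and 1 gene, Gm22133, lay under 0.4, so a candidate explanation is that tumour cells gave a large part of this RNA. The reverse ratio had a 1st percentile of 7.8e-04 over 4098 genes, so some genes abundant in sorted libraries were nearly absent from the tumour libraries. All 12 macrophage markers lay above the median T cell identity gene (612 against 39.3 CPM as list medians), which is consistent with macrophages in the sorted samples, although the labelled sort would remove them; whole tumour tissue under that label stays open.

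Cytotoxic genes were lower in the shFgf21 sorted libraries. The list includes Tnf, Ccl3 and Ccl4, whose RNA may come from other cells, so its level may not be that of T and NK cells alone. Dilution by more macrophage RNA would lower all T cell genes alike, yet the cytotoxic level minus the CD4 and regulatory T cell level differed by -0.85 between groups (pooled SD 0.21, exact permutation p = 0.1), without overlap. This cannot exclude dilution together with a shift among T cell subsets, since Cd8a was at -0.68 and Cd4 at 0.34, though neither passed. The difference was -0.47 relative to T cell identity (pooled SD 0.26, without overlap), -0.13 relative to NK cells (pooled SD 0.24, overlapping) and -0.30 relative to their mean (pooled SD 0.19), with exact permutation p = 0.1, 0.6 and 0.2 (two-sided, where 10 groupings allow no p under 0.1). Fewer T or NK cells may or may not account for it, and the 5 libraries are too few to tell. An effect of the knockdown on these cells stays open and untested.

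Some called genes took 2 separate levels, without regard to group, in the kind of sample where they were not called. Of 10 called genes with a mean of at least 5 CPM in both kinds of sample, 3 (Abl1, Gm20716 and Pcyt1a) split there, not along the groups. A split was a gap of over 0.75 log2 that was also over 2 times the wider range on either side. Among 9530 other genes, 1.62% split in tumours and 1.66% in sorted cells (Fisher exact p = 4.8e-04 against the rate in tumours). The other 7 also had a gap of 0.80 to 2.28 log2 but a wider spread beside it. Snord16a in tumours was at 9.03, 0.0491 and 0.0497 CPM in shNC and 0.0573, 6.33 and 6.13 CPM in shFgf21. Gm45713 in sorted cells was at 0, 0 and 3.03 CPM in shNC and 3.35 and 0 CPM in shFgf21. Both lay at separate levels but had a mean under 5 CPM in that kind of sample, so they were not scored. The pattern was seen in these genes before the definition was set, so this p restates it and decides nothing. A switch in the upstream assignment of reads to genes stays open, as does an exchange with an overlapping listed gene. For 3 of 18 called genes (Mir8114, Snord16a and Gm20716) such a gene moved the other way by at least 0.5 times their change in CPM. For Mir8114 and Snord16a it moved by 8.51 and 6.67 times, more than reads passing over could give, so this rule does not show an exchange. An effect of the knockdown on any called gene stays open and was not tested.

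The numbers of splits are too small for a share under 0.05. In tumours 1 of 10 splits, the real one, gave as many as 5 genes, and the highest other gave 1. For lists in tumours, 1 of 10 splits gave as many as 13, and the highest other gave 8. In sorted cells 1 of 10 splits into 3 and 2 libraries gave as many as 13 genes, and the highest other, with shNC replicates 1 and 2 against the rest, gave 12. For lists in sorted cells, 3 of 10 splits gave as many as the real 8, and the highest other gave 8, both with shNC replicates 1 and 2 against the rest and with shNC replicate 1 and shFgf21 replicate 2 against the rest.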

How the results depend on the processing

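Robust moderation and the fit with the T cell identity level as a covariate were chosen after seeing the data. In sorted cells the count of 13 genes was 1 without a filter, 246 by DESeq2, 1 with all 4 groups in one fit, 30 with robust moderation, 22 with the covariate and 0 to 34 without 1 library. In tumours the count of 5 was 1 with the filter at 5 CPM, 115 by DESeq2, 21 by voom, 26 with all groups in one fit, 8 with robust moderation and 0 to 8 without 1 library. For the interaction the count of 1 was 4 without a filter, 4 with robust moderation, 36 by DESeq2 and 0 to 4 without 1 library. A smaller filter set changes the adjustment by construction; otherwise the cause was not tested. Where a left-out library leaves 1 in an arm, it is assumed to vary like the others.

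Of the 8 lists called in sorted cells, 0 were called with an estimated correlation, 0 by fry and 4 to 11 without 1 library. Of the 13 in tumours, 0 were called with an estimated correlation and 1 by fry. The cytotoxic list, at a median of -0.86, was at -0.48 with the covariate (adjusted p = 6.0e-05) and at -1.01 to -0.65 without 1 library, and lost its call with an estimated correlation (adjusted p = 0.603) and by fry (0.229; 1.3e-07 to 0.603 over its alternatives). Prf1 was called in 8 of 13 alternatives (adjusted p from 1.3e-12 to 0.470), with a log2 fold change of -1.37 to -1.07 over them. Cholesterol biosynthesis in sorted cells had a median of 0.11 with the covariate (adjusted p = 0.00763) and of 0.084 to 0.16 without 1 library (adjusted p from 0.00763 to 0.656 over its alternatives). Without 1 library the sign turned for Tox (-0.30 to 0.41), Sqle in sorted cells (-0.062 to 0.39), Srebf1 (-0.011 to 0.21), Lgals4 (-0.42 to 0.17), Sqle in tumours (-0.037 to 0.40) and the exhaustion list (-0.027 to 0.22), and by voom for Cdh5 in tumours (0.46); none of these was past the threshold. On library totals the mean log2 level was 9.47 for macrophages and 6.67 for fibroblasts in shFgf21 sorted cells and -0.79 for T cell identity in shFgf21 tumours. The median-ratio scaling left the calls of lists at 8 and 13. Over all alternatives on named genes, 853 values in sorted cells and 857 in tumours kept their direction and side of the threshold, 34 and 56 newly passed it, and 59 and 3 no longer did.

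With the replicate number as a block, 131 genes were called in tumours, 46 higher and 85 lower. Of the 13 lists called in tumours, 3 lost their call with the block: glycolysis, integrated stress response and interferon-stimulated genes. The groups share only numbers 1 and 2, whose deviations correlated at 0.165 and -0.153 across genes. Over all pairs of an shNC and an shFgf21 tumour the correlation ran from -0.251 to 0.165. These values cannot decide whether a shared number means a pairing.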

Other observations

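Spp1, Cd36 and Il1b had lower means in the shFgf21 sorted libraries and did not pass the test. Spp1 was chosen after its values were seen, and the tests on genes at 2 levels were chosen after the result was seen. Spp1, osteopontin, was at 4621 ± 381 CPM in shNC and 2670 ± 70.2 CPM in shFgf21 (SD over 3 and 2 libraries, CPM scaled over all libraries), with a log2 fold change of -0.81 ± 0.12 (SE, edgeR adjusted p = 0.0824), and it was also at 1826 to 2308 CPM in the tumour libraries. The scavenger receptor gene Cd36 was at 120 ± 44.9 and 38.0 ± 12.4 CPM (log2 -1.65 ± 0.32, edgeR adjusted p = 0.162), and Il1b, an inflammatory cytokine, was at 327 ± 120 and 179 ± 28.7 CPM (-0.87 ± 0.27, adjusted p = 0.316). Cd36 belongs to the fatty acid oxidation list and Il1b to the cytokine and chemokine list, and neither list was called in sorted cells (camera adjusted p = 0.771 and 0.202).

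Genes at 2 levels were more common than chance in both kinds of sample together. Of 10802 genes with a mean of at least 5 CPM in both, 180 split in sorted libraries and 189 in tumours. In both kinds 43 split, against 3.15 by chance (Fisher exact p = 1.8e-37, across genes, which are not independent). Hmga1, Nek7 and Pcdhga9 were examples, chosen after their values were seen. Hmga1 was at 74.9 CPM in shNC sorted replicate 2 and at 390 to 447 CPM in the other sorted libraries, and at 191 CPM in shNC tumour 1 and 573 to 848 CPM in the other tumours. Pcdhga9 was at 137 CPM in shNC sorted replicate 2 and at most 0.137 CPM in the other sorted libraries, and at 234 and 222 CPM in shNC tumour 6 and shFgf21 tumour 3.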
